A study of Mus musculus with 6 samples.

How the data were processed

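RNA from sorted mouse lung epithelial cells was sequenced in 6 libraries, 3 from Kras-mutant cells labelled 4wTumour and 3 from cells of normal genotype labelled AEC2. Per the labels, lungs were perfused with cold buffer and dissociated for 30 minutes when normal and 45 minutes when they held neoplastic growth. Leucocytes were depleted with beads against CD45 and live cells were sorted by flow cytometry. The labels do not name the marker used for the sort, and they give the strain as mixed for all 6 libraries. Dissociation time went with the group. Libraries came from a stranded mRNA kit and were read as 50 bp single ends.

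The authors deposited 1 table of raw read counts per gene symbol, in whole numbers, for all 6 libraries. Per the labels, the authors used STAR and DESeq2 with the mm10 build, without versions or roles. The counting tool, the annotation, the use of strand and any filter were not stated. No column of per-sample values was left out. The table held 23420 genes, 5766 of them at 0 in every library. Totals ran from 21723727 to 44841679 counts, a 2.06-fold range.

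Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust dispersion and robust quasi-likelihood F test). The filter left 13545 genes, which held 99.97% of the counts. The model held the group alone and had 4 residual degrees of freedom. Fold changes are Kras mutant over normal. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The common dispersion was 0.0821 and the median biological coefficient of variation 0.245. Levels are TMM-scaled CPM with the SD over 3 libraries, and errors of log2 fold changes are standard errors (SE). Sample correlations and principal components used log2 CPM with a prior count of 2.

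Before the data were examined, 37 gene lists with 722 genes, the rule for naming genes, the tests and a first set of alternatives were written down. No gene was in more than 1 list. Each list with at least 5 measured members, 31 in all, was tested with camera in limma 3.58.1, with an inter-gene correlation preset at 0.01. Adjustment was over those 31 lists. Beside it, camera was run with the correlation estimated for each list, and the rotation test fry. Camera compares a list with all other genes, while fry asks whether the genes of a list move, on balance, in 1 direction. Fry called 7 lists higher and 6 lower, and its p is given where its call differed from that of camera. Members were also counted after adjustment over the list alone.

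Genes were named by that rule. It took the 5 largest rises and 5 largest falls among called genes with a mean of at least 3 on the log2 CPM scale and groups that did not overlap. It took the 2 called members with the largest change of each primary list and 1 of each other list, at that same mean. Where no member met this, the member with the highest mean was taken. A fixed set that included Kras, Sftpc and Mki67 was always named. In all, 63 genes were named. Further genes, where a count of 5 or fewer is spelled out, were chosen after their values were seen.

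Gene positions, GC content, transcript length and overlaps came from GENCODE M21 on GRCm38, the assembly that mm10 also denotes. GC content and length were found for 99.3% of the tested genes. For each named gene, every 50-base stretch of its longest transcript was compared with the transcripts of all other genes, on both strands, since the use of strand in counting was not stated. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1, so genes were tested only with the model across all genes.

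The procedure was tested on simulated data with the same library sizes and dispersion. It found 0 of 50 genes changed 1.5-fold, 10 of 50 changed 2-fold, 43 of 50 changed 4-fold and 48 of 50 changed 8-fold. Of 13267 unchanged genes it called 4. A list raised 2-fold was called and 0 of the other lists were. Genes were drawn independently, so the simulation held no correlation between genes, no GC trend and no normal library set apart. In the real data the estimated correlation within a list reached 0.92, for mitosis. The simulated error counts, above all those of lists, thus need not hold for the real libraries. Only 50 genes at each fold were changed, all with a mean above 0 on the log2 CPM scale. In the real data 2588 genes were called, which makes the adjusted threshold easier to pass. The shares of changed genes found thus need not hold there either. Intervals for ratios of genes with 3 or fewer normal counts are at the 95% level and cover counting error only. Reads without molecular identifiers are not independent molecules.

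The first set of alternatives held DESeq2 size factors (RLE), library size alone, no filter, a filter of at least 100 counts in 3 libraries, DESeq2 1.42.0 with its Wald test, limma-voom, the replicate number as a block, leaving out each library in turn, and a minimum log2 change of 1. After the data were seen, 4 alternatives were added. They were an offset for GC content and transcript length, that offset with the replicate block, normal replicate 1 as the only normal library, and normal replicate 1 left out with that offset. The offset was a natural spline with 5 degrees of freedom for each property and library. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Alleles, splicing and chromatin were not analysed here.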

Results

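Gene expression was measured in 6 libraries of sorted mouse lung epithelial cells, 3 Kras-mutant and 3 of normal genotype. The labels name the mutant cells 4wTumour and the normal cells AEC2. The title of the series names proliferation and plasticity of lung epithelium under oncogenic Kras. The comparison therefore asked which genes, cell states and pathways differed between mutant and normal cells. Mutant replicates 1 to 3 held 41659480, 37229690 and 33194159 counts. Normal replicates 1 to 3 held 44841679, 21723727 and 25915088. Between 15115 and 16380 genes were detected per library. Sftpc, which encodes surfactant protein C of alveolar type 2 cells, was the most abundant gene in the 3 mutant libraries and normal replicate 1, at 3.85 to 4.47% of counts. Sftpb, another surfactant protein gene, was the most abundant in normal replicates 2 and 3, at 2.35 and 2.53%.

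The 3 mutant libraries resembled each other closely, while normal replicate 1 stood apart from them and from the other normal libraries. Spearman correlations over the tested genes were 0.991 to 0.995 among mutant libraries and 0.990 between normal replicates 2 and 3. Normal replicate 1 correlated at 0.941 and 0.952 with normal replicates 2 and 3, and at 0.955 to 0.964 with the mutant libraries. The first principal component, with 77.3% of the variance, placed the mutant libraries at -72.1, -58.2 and -64.2. It placed normal replicates 1 to 3 at 12.1, 96.8 and 85.6. The second placed normal replicate 1 at -58.9 and the other 5 libraries at 8.60 to 16.4. Across genes, the difference of normal replicates 2 and 3 from normal replicate 1 correlated with GC content at a Spearman rho of -0.450, against at most 0.113 in absolute size for the other differences within a group. Genes are not independent replicates, so this carries no p. The difference of the mutant mean from the normal mean, on which the fold changes rest, correlated with GC content at 0.332 and with transcript length at -0.296. Taken from normal replicates 2 and 3 alone it correlated at 0.364 and -0.304, and from normal replicate 1 alone at 0.0875 and -0.180. The separation of the samples, taken as the lowest correlation within a group minus the highest between groups, was -0.0227, and 0.0790 without normal replicate 1.

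Kras itself, the gene named in the genotype label, stood at 143, 150 and 139 CPM in mutant replicates 1 to 3. In normal replicates 1 to 3 it stood at 172, 322 and 279 CPM. Its log2 fold change was -0.84 ± 0.24 (SE, n = 3 per group), and it did not pass the test (adjusted p = 0.0504). Kras lies on chromosome 6 at 145216699 to 145250239 on the minus strand of GRCm38. The total count of a gene does not show which allele is expressed, so these values do not check the genotype. Without normal replicate 1 the log2 fold change was -1.05 and the adjusted p 8.22e-05, and over all alternatives the adjusted p ran from 8.22e-05 to 0.165.

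Mutant and normal libraries differed at 2588 genes, of which 820 were higher and 1768 lower in mutant libraries. Endothelial and fibroblast markers were among those lower, 18 of 20 and 13 of 17 being called, so a fall need not lie within epithelial cells. Among the genes named by rule, the largest rise was that of Dlk1, an imprinted gene for a Notch-like transmembrane protein (chromosome 12, 109452823 to 109463336). It rose from 0.0512 ± 0.0887 to 17.4 ± 13.9 CPM (SD, n = 3), with only 7 normal reads. Rian, a noncoding RNA of the same imprinted locus (109603940 to 109661716), rose 35.7-fold from 2.40 ± 1.38 to 85.4 ± 17.1 CPM. Ereg, which encodes the growth factor epiregulin (chromosome 5, 91074622 to 91093646), rose 79.2-fold from 0.574 ± 0.370 to 47.7 ± 17.9 CPM. St8sia6, a sialyltransferase gene, rose 77.7-fold, and Cldn4, a tight junction claudin (chromosome 5, 134945119 to 134946934), rose 39.7-fold. The log2 fold change of Cldn4 was 5.31, and ran from 4.50 to 6.12 over 17 alternatives. Hpgd, whose product breaks down prostaglandins (chromosome 8, 56294585 to 56321043), fell the most, from 470 ± 248 to 9.38 ± 3.26 CPM. Aff3 was 42.5-fold lower and Ms4a4d 41.8-fold lower. Figf, the gene for vascular endothelial growth factor D, was 40.3-fold lower, and Ogn, an extracellular matrix proteoglycan gene, 38.6-fold lower. Over 17 alternatives the log2 fold change of Ms4a4d ran from -5.83 to -3.52, that of Figf from -5.85 to -3.60 and that of Ogn from -5.83 to -3.19. The adjusted p of these 10 genes lay between 0.00129 and 0.0134.

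The groups did not overlap in 51.2% of the tested genes, where chance gives 10%, and in 2585 of the 2588 called genes. By unadjusted p, 5845 genes passed 0.05. The counts changed when 1 library was left out. Leaving out any 1 mutant library left 189 to 200 genes higher and 471 to 599 lower. Without normal replicate 2 or 3 there were 320 or 247 higher and 983 or 852 lower. These fits had fewer libraries and so less power, which alone lowers the counts. In them 0 genes were called in the direction opposite to that with all libraries. Without normal replicate 1 there were 4715 higher and 4458 lower. Ms4a4d lost its call without mutant replicate 1 (adjusted p = 0.0502) and Ogn without mutant replicate 3 (adjusted p = 0.0695). With normal replicate 1 as the only normal library, Dlk1, Cldn4 and Ogn were not called (adjusted p = 0.129, 0.117 and 0.064).

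**Figure D1:**
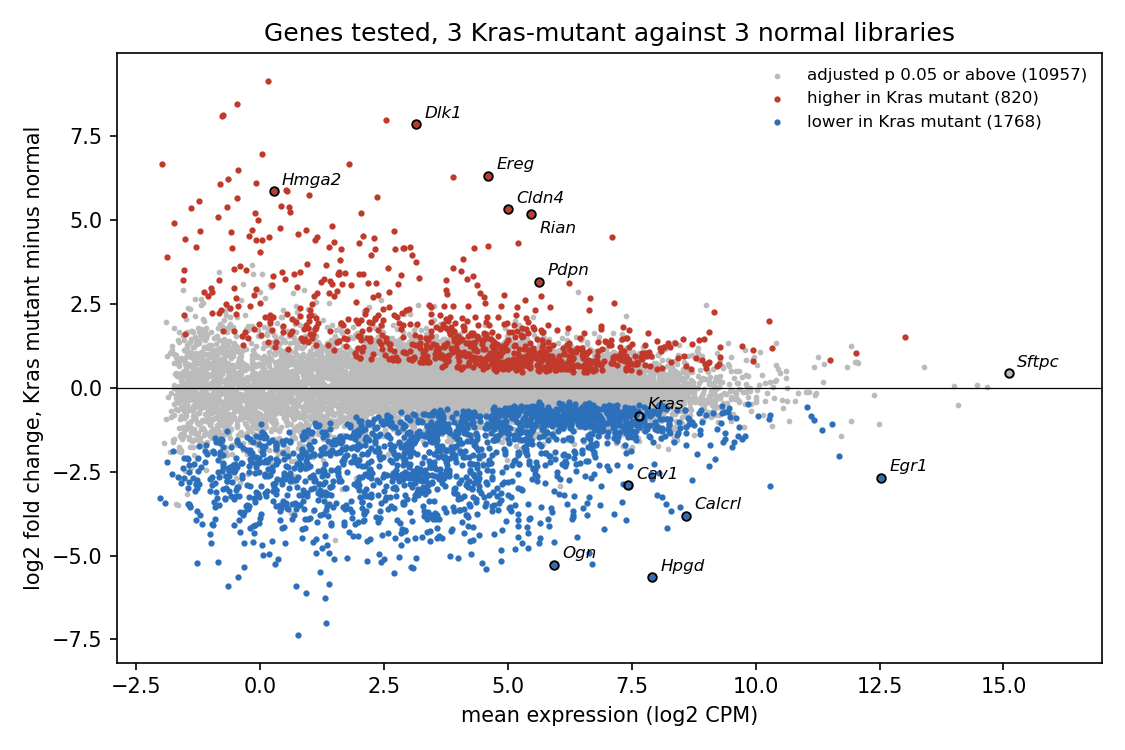
Mean expression (log2 CPM, horizontal) against log2 fold change of Kras-mutant over normal cells (vertical) for 13545 genes, each a point, with 820 genes called higher in red, 1768 called lower in blue and the rest in grey. Of the named genes some are circled, from Dlk1 at 7.84 to Hpgd at -5.65.

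Of 24 measured genes of a transitional alveolar state, seen when type 2 cells change toward type 1 cells, 12 rose and 2 fell in mutant cells. The median log2 fold change was 1.26, and 0.75 with a correction for GC content and length, chosen after the data were seen. Cldn4 rose from 1.5 ± 1.11 to 62.1 ± 48.2 CPM, and Sprr1a, a cornified envelope gene, rose 7.57-fold from 3.13 ± 1.45 to 23.5 ± 19.9 CPM (SD, n = 3). Krt8, a keratin of simple epithelia, stood at 241 ± 39.6 in mutant and 125 ± 46.5 CPM in normal cells and missed the threshold (adjusted p = 0.0569). Type 1 cell markers went both ways, with 2 higher and 8 lower of 25. Pdpn, which encodes podoplanin of the type 1 cell surface (chromosome 4, 143267431 to 143299564), rose 8.89-fold from 9.94 ± 1.2 to 88.4 ± 9.56 CPM. Cav1, a caveolin of type 1 and endothelial cells (chromosome 6, 17306335 to 17341452), was 7.44-fold lower, at 40.6 ± 3.71 against 302 ± 86.6 CPM.

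Camera called the transitional list higher (adjusted p = 8.34e-06), but not with an estimated correlation (adjusted p = 0.555). Adjusted over the list alone, 17 of its members were higher and 3 lower. For the type 1 list the median was -0.22 and the adjusted p 0.298 by camera (lower in 1 of 16 alternatives, over which the adjusted p ran from 0.0135 to 0.617), while fry called it lower (adjusted p = 0.0183), with 3 members higher and 9 lower when adjusted over the list alone. Endothelial markers, which moved with Cav1, had a median log2 fold change of -2.95. Hopx, a type 1 cell transcription regulator, had a log2 fold change of 0.63 ± 0.18 (adjusted p = 0.0525), and 27.2% of its exon bases lie opposite another gene. Sprr1a lost its call in 8 of 17 alternatives, 4 of which left out 1 library (adjusted p up to 0.205 over all). Its log2 fold change, 2.92 with all libraries, ran from 1.82 to 3.32. Krt8 shares 29.7% of its 50-base stretches with other genes. Krt8 passed in 6 and Hopx in 4 of 17 alternatives (adjusted p over all from 0.000797 to 0.166 and from 0.000271 to 0.171).

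Type 2 cell identity genes were called as a group neither by camera nor by fry. Of 28 measured members 4 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 0.09 (adjusted p = 0.298). The 4 that rose were Abca3 (0.81), Lpcat1 (1.17), Acoxl (1.34) and Rab27a (1.03, all log2), of which Abca3, Lpcat1 and Rab27a were chosen after their values were seen. Acoxl, an acyl-CoA oxidase-like gene, rose 2.52-fold, from 187 ± 32.9 to 473 ± 121 CPM. Pla2g1b, a secreted phospholipase gene, was 4.18-fold lower, at 42.0 ± 7.02 against 176 ± 102 CPM. Sftpc stood at 40517 ± 3671 CPM in mutant and 30288 ± 9757 CPM in normal cells (log2 fold change 0.42, adjusted p = 0.234). Nkx2-1, a lung lineage transcription factor, stood at 547 ± 31.9 and 947 ± 347 CPM (log2 fold change -0.79, adjusted p = 0.0888).

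Of 18 general epithelial genes 3 rose and 1 fell, and 7 and 3 did when adjusted over the list alone (median 0.25, adjusted p = 0.298 by camera; higher by fry, adjusted p = 0.0467). Epcam, an epithelial adhesion gene, rose 1.39-fold (adjusted p = 0.0467), and Spint1 and St14, chosen after their values were seen, also rose. Foxa1, a transcription factor of lung epithelium, fell by 1.48 ± 0.40 on the log2 scale (adjusted p = 0.0466). Of 17 alternatives Acoxl lost its call in 3 (adjusted p up to 0.0691), Pla2g1b in 7 (adjusted p up to 0.136), Epcam in 12 (adjusted p up to 0.378) and Foxa1 in 9 (adjusted p up to 0.298). The last 3 lost it without any 1 library other than normal replicate 1, and the smallest log2 fold changes were 0.11 for Epcam and -0.28 for Foxa1. Over 17 alternatives the log2 fold change of Sftpc took both signs, from -0.31 to 0.72, and 1 called it higher, the one without normal replicate 1. That of Nkx2-1 ran from -1.62 to -0.01, and 3 called it lower.

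**Figure D2:**
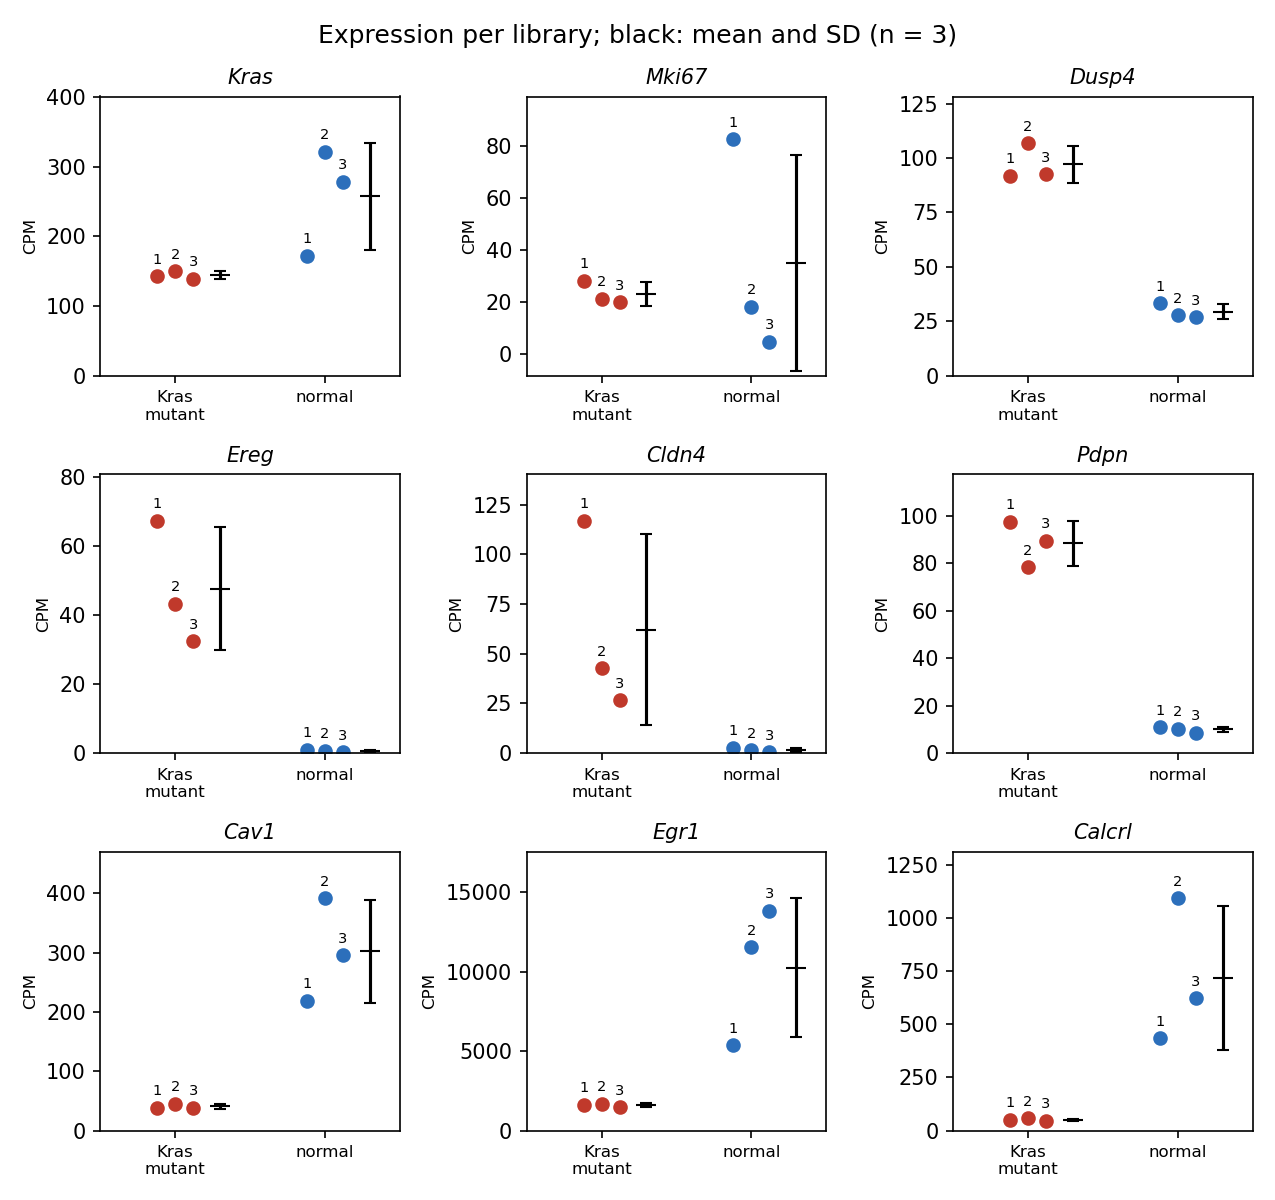
Expression in CPM (vertical) of 9 named genes in each library, in red for Kras-mutant and blue for normal cells, with the replicate number at each point and the mean and SD of the 3 libraries in black. Pdpn lies at 88.4 CPM in mutant and 9.94 in normal cells, and Mki67 is spread from 4.87 to 82.3 CPM among the normal libraries.

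Proliferation genes were highest in normal replicate 1 and did not pass the test as a group. Of 30 measured mitosis genes 0 rose and 0 fell, with a median log2 fold change of -0.38. The mean of these genes was 2.27, 1.86 and 2.03 on the log2 CPM scale in mutant replicates 1 to 3, and 3.48, 0.98 and 0.03 in normal replicates 1 to 3. Mki67, which encodes the proliferation antigen Ki-67, stood at 82.3, 18.3 and 4.87 CPM in normal replicates 1 to 3 and at 23.2 ± 4.45 CPM in mutant cells (log2 fold change -0.61 ± 0.86, adjusted p = 0.602). Of 31 DNA replication genes 0 rose and 2 fell, namely Pcna, the replication clamp, and Ccne2, a cyclin chosen after its values were seen. Pcna was 1.61-fold lower, at 28.0 ± 2.11 against 45.0 ± 4.95 CPM, and shares 31.8% of its 50-base stretches with a pseudogene.

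For mitosis, camera gave the direction up (adjusted p = 0.490) although the median and mean of the edgeR fold changes were negative. Those fold changes lie near the ratio of average CPM, in which the high values of normal replicate 1 weigh most. By limma-voom, on log2 values, the mitosis median was 0.28 (camera, adjusted p = 0.468). For DNA replication camera gave down (median -0.25, adjusted p = 0.817). By edgeR 0 mitosis genes were also called when adjusted over the list alone. The mitosis list was higher in mutant cells without normal replicate 1, with a median log2 fold change of 1.54 (adjusted p = 0.00903). With normal replicate 1 as the only normal library its median was -1.56, and that of DNA replication was -0.97. Over 16 alternatives the DNA replication median took both signs, from -0.97 to 0.62. Over the alternatives the adjusted p of the mitosis list ran from 1.65e-15 to 0.875. Pcna lost its call in 6 of 17 alternatives, 5 of which left out 1 library (adjusted p up to 0.12).

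**Figure D3:**
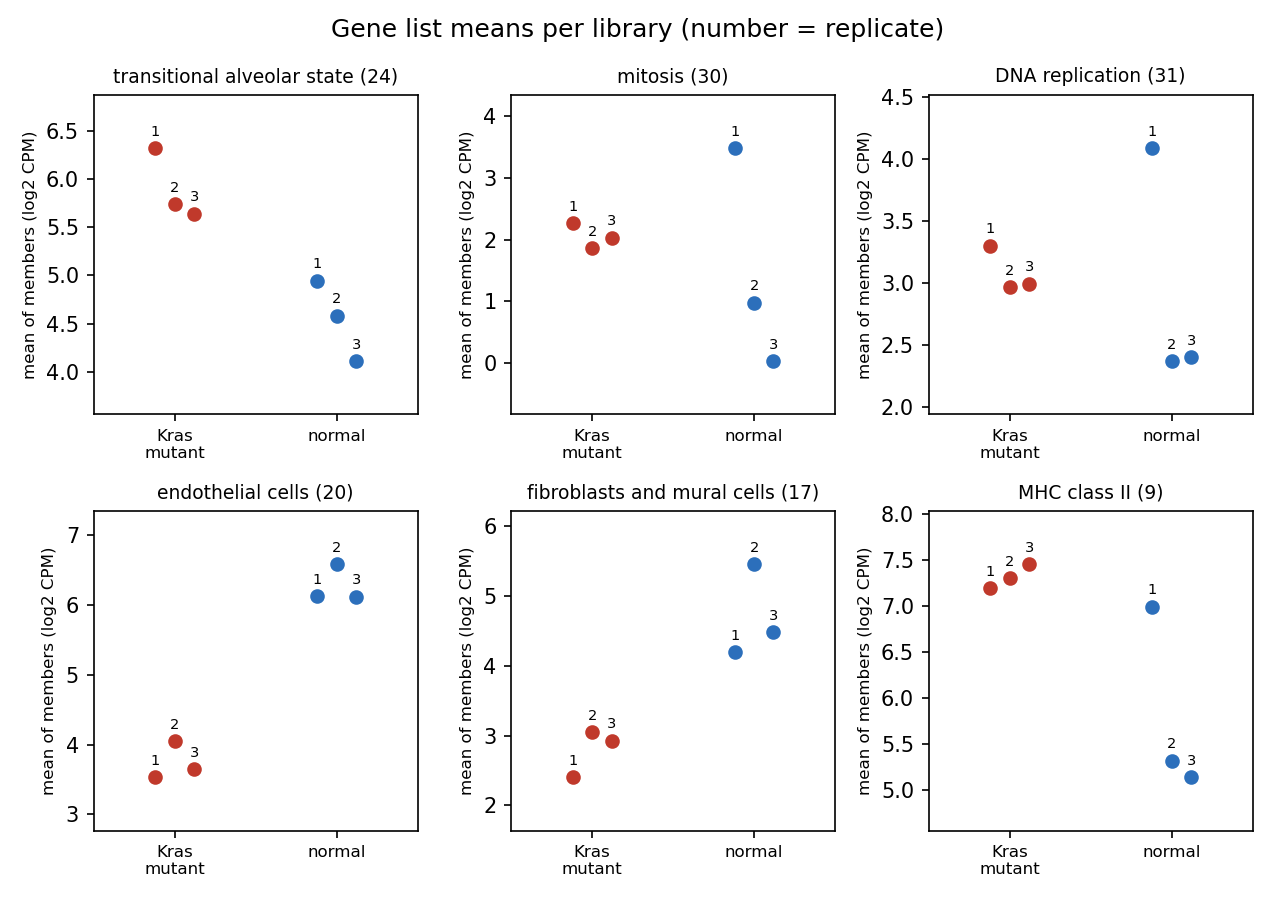
Mean of the measured members (log2 CPM, vertical) of 6 gene lists in each library, in red for Kras-mutant and blue for normal cells, with the replicate number at each point. Normal replicate 1 has the highest mean of the mitosis list, 3.48, and the endothelial means of the 3 normal libraries, 6.12 to 6.58, lie above those of the mutant libraries, 3.53 to 4.05.

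Of 19 measured genes that report signalling through ERK, the kinase downstream of Kras, 9 rose and 1 fell in mutant cells, with a median log2 fold change of 0.61. Dusp4, a phosphatase that acts on ERK (chromosome 8, 34807297 to 34819894), rose 3.31-fold from 29.3 ± 3.47 to 97.1 ± 8.52 CPM (SD, n = 3). Dusp6, another ERK phosphatase, rose 2.10-fold, and Ccnd1, which encodes cyclin D1, rose 2.73-fold from 266 ± 120 to 727 ± 31.8 CPM. Of 26 AP-1 and immediate early genes 10 fell and 1 rose, with a median of -0.62. Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984), was 6.42-fold lower, at 1597 ± 121 against 10253 ± 4380 CPM, and Egr2 was 4.13-fold lower. The 1 that rose was Cyr61, a matrix-associated gene chosen after its values were seen. Of 11 EGFR family genes, Ereg and Epgn, both ligands, rose and Egfr, the receptor, fell, of which Epgn and Egfr were chosen after their values were seen.

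Camera called ERK output higher (adjusted p = 0.0113; 0.555 as the adjusted p with an estimated correlation). It called the EGFR family higher (median 0.39, adjusted p = 0.0324; adjusted p = 0.555 with an estimated correlation). The immediate early list was called lower (adjusted p = 0.0143; adjusted p = 0.601 with an estimated correlation). Adjusted over the list alone, the members higher and lower were 10 and 2 for ERK output, 3 and 1 for the EGFR family and 3 and 11 for immediate early genes. Without normal replicate 1 all 3 calls were lost, at adjusted p = 0.202, 0.354 and 0.195 for ERK output, the EGFR family and immediate early genes, whose medians were then 0.71, 0.47 and -0.24. With the GC and length correction added, the first 2 were still not called (medians 0.59 and 0.84, adjusted p = 0.281 and 0.146), while immediate early genes were called lower (median -1.03, adjusted p = 0.000104). Without mutant replicate 1 the last 2 were lost at adjusted p = 0.0514 and 0.0684, and a stricter filter left 8 EGFR family genes, not called (median 0.28, adjusted p = 0.187). Dissociation lasted 45 minutes for lungs with neoplastic growth and 30 minutes for normal lungs. Ccnd1 lost its call without normal replicate 2 or any 1 mutant library, and Dusp6 without any 1 mutant library (adjusted p = 0.0602 to 0.117). Ccnd1 shares 27.2% of its 50-base stretches with a gene on the other strand. Fosl1, an AP-1 subunit gene, stood at 6.44 ± 1.96 against 3.24 ± 1.17 CPM (adjusted p = 0.0831; higher in 1 of 17 alternatives), and 58.9% of its stretches are shared with a gene on the other strand.

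Some genes of the embryonic lung tip and of gastric and gut lineages rose in mutant cells. Of 14 measured tip progenitor genes 5 rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 0.57. The 5 were Mycn, Hmga2, Dlk1, Cldn6 and Sox4, and the 2 were Igf2 and Sox11; Mycn, Cldn6, Sox4 and Sox11 were chosen after their values were seen. Hmga2, a chromatin protein of embryonic tissue, was 67.1-fold higher (95% interval from 22.7 to 327) with 256 mutant and 3 normal reads. Igf2, a growth factor gene, was 14-fold lower, at 1.58 ± 0.204 against 22.1 ± 12.1 CPM, and 76.0% of its 50-base stretches are shared with an overlapping gene. Sox9 stood at 2.19 ± 0.604 against 0.878 ± 0.632 CPM (adjusted p = 0.124; higher in 1 of 16 alternatives) and Id2 at 141 ± 14.8 against 142 ± 22.5 CPM (adjusted p = 0.983). Of 10 measured gastric and gut genes 4 rose and 0 fell, namely Hnf4a, Gkn2, Onecut2 and Cldn2, chosen after their values were seen. None of the 4 reached the mean of 3 on the log2 CPM scale that the naming rule asked for. The mean of the 10 genes was low, at 0.94, 1.02 and 0.68 on that scale in mutant replicates 1 to 3. In normal replicates 1 to 3 it was -1.04, -0.86 and -0.69. Hnf1b, the list's most abundant member, stood at 64.7 ± 3.84 against 101 ± 44.4 CPM (adjusted p = 0.177). Normal replicate 1 had 51.0 CPM of it, below every mutant library (61.4 to 68.9), and over 17 alternatives its log2 fold change took both signs, from -1.44 to 0.35.

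Camera did not call the tip progenitor list (adjusted p = 0.0827, and from 0.0193 to 0.879 over 16 alternatives, of which 3 called it higher), while fry called it higher (adjusted p = 0.0453). Camera called the gastric and gut list higher (median 2.09, adjusted p = 0.0113), but not with an estimated correlation (adjusted p = 0.418) or without normal replicate 1 (adjusted p = 0.427), where the median was 2.61. Adjusted over the list alone, 5 of its members were higher and 1 lower. Only 10 of its 24 genes passed the filter on low counts, and too few passed the stricter filter for the list to be tested. The stricter filter left 10 tip progenitor genes, with a median of -0.09 (adjusted p = 0.707 by camera).

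Wnt and matrix genes went both ways in mutant cells. Of 12 measured Notch pathway genes 8 fell and 0 rose, also when adjusted over the list alone, with a median log2 fold change of -1.02. Notch4, a receptor known from endothelium (chromosome 17, 34564268 to 34588503), was 6.82-fold lower, at 8.61 ± 2.10 against 58.6 ± 15.5 CPM (SD, n = 3). Of 16 genes of the Wnt target list, which also holds Wnt ligands and other parts of the pathway, 1 rose and 6 fell. Axin2, a target and feedback inhibitor of Wnt signalling, was 2.50-fold lower. The 1 that rose was Wnt7a, a ligand and not a target, and Wnt3a, also a ligand, was among the 6 that fell. Both ligands were chosen after their values were seen. Of 23 matrix and invasion genes 5 rose and 6 fell. The 5 were Lamc2, Itga2, Itgb4, Plau and Adam8, chosen after their values were seen, which encode a laminin chain, integrins and proteases. Zeb2, a transcription factor of mesenchymal cells, was 27.5-fold lower, at 2.96 ± 0.876 against 81.7 ± 56.6 CPM. Of 18 YAP and TGF-beta targets 3 rose and 3 fell, also when adjusted over the list alone, with Ltbp1, which encodes a TGF-beta binding protein of the matrix, 8.99-fold lower.

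Camera called the Notch list lower (adjusted p = 8.36e-05), but not with an estimated correlation (adjusted p = 0.418). It did not call the others. The Wnt list had a median of -0.64 (adjusted p = 0.167 by camera). Fry called it lower (adjusted p = 0.00928). Camera did so in 2 of 16 alternatives, over which its adjusted p ran from 0.0281 to 0.296. Matrix and invasion genes had a median of -0.02 (adjusted p = 0.948 by camera). For the YAP and TGF-beta list the median was 0.05 and the mean -0.04 (adjusted p = 0.989). Adjusted over the list alone, 3 members of the Wnt list were higher and 9 lower, and 7 matrix genes were higher and 7 lower. Endothelial and fibroblast markers fell in these same libraries, with medians of -2.95 and -1.91.

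Some lipid genes were called, as were 2588 of all 13545 tested genes. Of 26 measured genes of fatty acid and phospholipid synthesis 3 rose and 3 fell, also when adjusted over the list alone, with a median log2 fold change of 0.04. Elovl1, which encodes an elongase of very long-chain fatty acids (chromosome 4, 118428093 to 118432953), rose 3.95-fold from 499 ± 158 to 1972 ± 350 CPM (SD, n = 3), and Fasn and Me1 rose. Gpam, which encodes the first enzyme of glycerolipid synthesis, was 2.86-fold lower, and Elovl6 and Lpin1 fell. Of 24 cholesterol synthesis genes 0 rose and 3 fell, namely Nsdhl (2.70-fold lower), Fdft1 (2.20-fold lower) and Insig1. Of 16 glycolysis genes 0 rose and 1 fell, Pdk1, a kinase that restrains pyruvate use (1.90-fold lower). Fasn, Me1, Elovl6, Lpin1 and Insig1 were chosen after their values were seen.

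None of these 3 lists was called by camera, with adjusted p of 0.490 for fatty acids, 0.0802 for cholesterol (median -0.36; lower in 5 of 16 alternatives, over which the adjusted p ran from 0.004 to 0.376) and 0.298 for glycolysis (median 0.42). Adjusted over the list alone, 2 cholesterol and 0 glycolysis genes fell. Fdft1 lost its call in 6 and Pdk1 in 8 of 17 alternatives (adjusted p up to 0.132 and 0.128), and Fdft1 shares 30.7% of its 50-base stretches with other genes. Gapdh, a glycolysis gene chosen after its values were seen, was counted at 1.3 ± 0.174 and 1.01 ± 0.405 CPM. It shares 27.8% of the 50-base stretches of its longest transcript with pseudogenes, and how shared reads were counted was not stated, so this value need not give its expression.

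Stress genes rose in part. Of 18 NRF2 targets, genes of the antioxidant response, 4 rose and 0 fell, with a median log2 fold change of 0.48. The 4 were Abcc4, a multidrug transporter (3.42-fold, from 17.7 ± 4.57 to 60.4 ± 8.08 CPM), and Slc7a11, Cbr3 and Hmox1, chosen after their values were seen. Of 22 p53 targets and senescence genes 7 rose and 4 fell. Gdf15, a stress cytokine gene, rose 10.1-fold from 3.39 ± 3.85 to 35.4 ± 10.03 CPM (SD, n = 3). Its log2 fold change was 3.33, and ran from 2.18 to 4.90 over 17 alternatives. Cdkn2a, which encodes the tumour suppressors p16 and p19, was 42.0-fold higher (95% interval from 11.4 to 352) with 107 mutant and 2 normal reads. The 4 that fell were Sesn1, Fas, Pmaip1 and Rrm2b, all p53 targets chosen after their values were seen.

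Camera called NRF2 targets higher (adjusted p = 0.00156), but not with an estimated correlation (adjusted p = 0.555), and 5 were higher when adjusted over the list alone. Camera did not call the p53 list (median 0.20, adjusted p = 0.207; higher in 1 of 16 alternatives), with 9 members higher and 5 lower when adjusted over the list alone. Gdf15 lost its call in 5 of 17 and Cdkn2a in 3 of 16 alternatives (adjusted p up to 0.098 and 0.0651).

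Interferon response genes fell in part, and no MHC class II gene passed the test singly. All 9 measured MHC class II genes had positive log2 fold changes, with a median of 1.12, and the mean of the list was 6.99 on the log2 CPM scale in normal replicate 1, 5.31 and 5.13 in normal replicates 2 and 3 and 7.19 to 7.45 in mutant libraries. Cd74, the invariant chain, stood at 4418 ± 496 CPM in mutant cells and at 4426, 2051 and 2262 CPM in normal replicates 1 to 3 (adjusted p = 0.179). Without normal replicate 1 it passed, at a log2 fold change of 1.05 (adjusted p = 0.000461), but not with the GC and length correction as well (0.23, adjusted p = 0.138). Of 24 interferon response genes 9 fell and 1 rose, with a median of -0.71. Oasl2, an antiviral gene, was 3.60-fold lower, at 9.09 ± 3.42 against 32.9 ± 13.3 CPM (SD, n = 3), and Oas3, chosen after its values were seen, was the 1 that rose. Of 19 inflammatory cytokine and NF-kB genes the neutrophil attractants Cxcl3 and Cxcl5, chosen after their values were seen, rose. Csf1, a growth factor of macrophages, was 6.24-fold lower and the 1 that fell.

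Camera called MHC class II higher (adjusted p = 0.0113), but not with an estimated correlation (adjusted p = 0.601) or with normal replicate 1 as the only normal library (adjusted p = 0.114). The list's median was 1.995 without normal replicate 1 (adjusted p = 1.03e-05) and 1.63 with the correction as well (adjusted p = 0.000195). By edgeR 0 MHC class II genes were also called when adjusted over the list alone. Camera called the interferon response lower (adjusted p = 0.0167; adjusted p = 0.601 with an estimated correlation), with 1 member higher and 12 lower when adjusted over the list alone. Fry called neither list (adjusted p = 0.0976 and 0.0609). The interferon call was lost in 4 of 16 alternatives, among them without normal replicate 1 (adjusted p = 0.202) and without mutant replicate 2 (adjusted p = 0.0667), and Oasl2 lost its call in 7 of 17 (adjusted p up to 0.159). Camera did not call the inflammatory list (median 0.80, adjusted p = 0.0749), with 2 members higher and 1 lower also when adjusted over the list alone. Of 16 alternatives 5 called it higher, with an adjusted p over all 16 from 0.0229 to 0.873. Its median was 0.19 with normal replicate 1 as the only normal library and 1.65 without that library (adjusted p = 0.0362), a call lost with the GC and length correction as well (adjusted p = 0.0811).

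The title of the series also names an epigenetic basis, and of 42 measured chromatin regulators 8 fell and 0 rose. Ep300, which encodes a histone acetyltransferase (chromosome 15, 81585351 to 81652077), was 2.55-fold lower, at 193 ± 12.7 against 494 ± 192 CPM (SD, n = 3). The list's median log2 fold change was -0.21 and camera did not call it (adjusted p = 0.0802), and 11 members were lower when adjusted over the list alone. Of 16 alternatives 2 called it lower, limma-voom (adjusted p = 0.0368) and the one without normal replicate 1 (adjusted p = 0.00585), the latter not with the GC and length correction as well (adjusted p = 0.087). With that correction alone the median was -0.12 (adjusted p = 0.417). Ep300 lost its call without any 1 library other than normal replicate 1 (adjusted p = 0.0816 to 0.117), and stood at 277, 562 and 643 CPM in normal replicates 1 to 3.

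**Figure D4:**
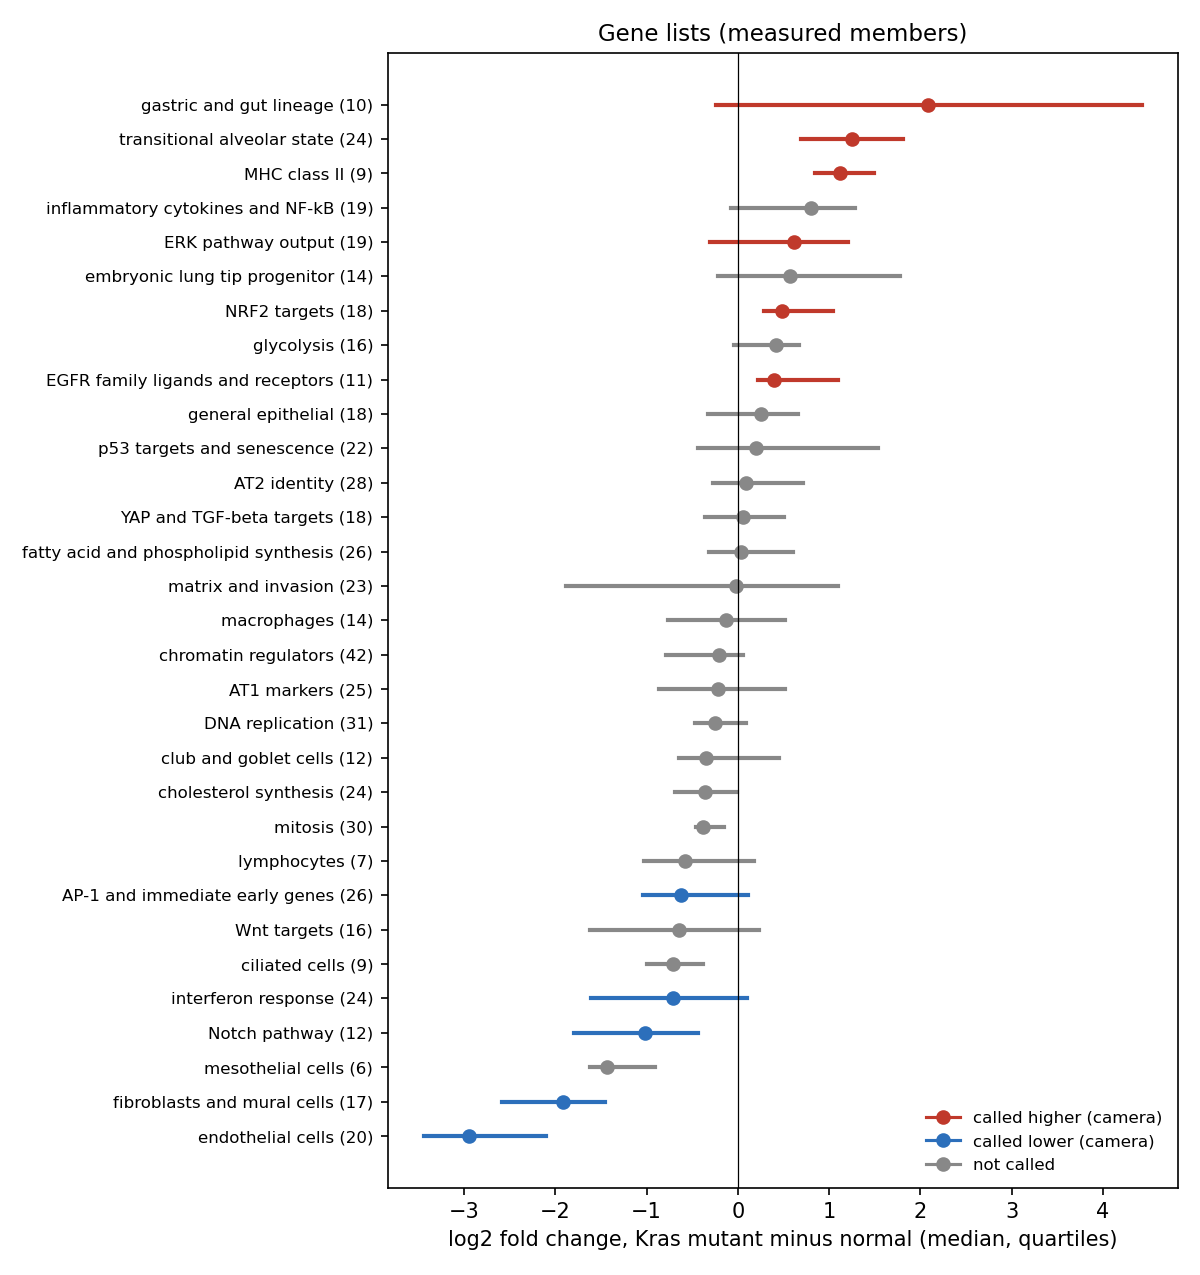
Median (point) and quartiles (line) of the log2 fold change of Kras-mutant over normal cells (horizontal) for the measured members, numbered in brackets, of 31 gene lists. Lists called higher by camera are red (6), those called lower are blue (5), and the medians run from 2.09 for the gastric and gut list to -2.95 for the endothelial list.

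Markers of endothelium and of fibroblasts and mural cells were far lower in mutant libraries. Of 20 endothelial markers 18 fell and 0 rose, with a median log2 fold change of -2.95. Calcrl, a peptide receptor gene (chromosome 2, 84330626 to 84425411), was the most abundant of those that fell, at 718 ± 340 CPM in normal and 51.1 ± 5.30 CPM in mutant libraries, 14.1-fold lower. Of 17 fibroblast and mural cell markers 13 fell and 0 rose, with a median of -1.91, and Inmt, a methyltransferase gene of lung fibroblasts, was 12-fold lower at 9.05 ± 4.95 against 109 ± 41.3 CPM (SD, n = 3). The endothelial mean was 3.53, 4.05 and 3.65 on the log2 CPM scale in mutant replicates 1 to 3 and 6.13, 6.58 and 6.12 in normal replicates 1 to 3. Of 6 measured mesothelial markers 1 fell, Upk1b (14.7-fold lower). Of 14 macrophage markers 2 fell, namely Lpl, a lipase gene also made outside macrophages (10.7-fold lower), and Cd68, chosen after its values were seen.

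Camera called the endothelial list lower (adjusted p = 3.35e-28; adjusted p = 0.354 with an estimated correlation), with 19 members lower when adjusted over the list alone. It called the fibroblast list lower (adjusted p = 2.44e-06; adjusted p = 0.555 with an estimated correlation), with 15 lower when adjusted over the list alone. Both calls were made in every alternative that used the preset correlation. Mesothelial cells had a median of -1.43 (adjusted p = 0.13) and were called lower in 1 of 15 alternatives. Macrophages had a median of -0.13 (adjusted p = 0.493), which took both signs over 15 alternatives, from -1.32 to 0.41. For both lists the counts were the same when adjusted over the list alone. Upk1b lost its call in 4 of 16 alternatives (adjusted p up to 0.0954). Its log2 fold change, -3.88 with all libraries, ran from -4.49 to -2.01.

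Markers of other airway and blood cells mostly did not pass the test. Of 12 club and goblet cell genes 1 rose, Scgb3a1, a secretoglobin chosen after its values were seen, and 1 fell, Aldh1a7 (1.43-fold lower), with a median of -0.35 and a mean of -0.02 (adjusted p = 0.817). Of 9 ciliated cell genes 1 fell, Dynlrb2, a dynein light chain (2.51-fold lower; median -0.71, adjusted p = 0.167). Camera called the ciliated list lower in 2 of 15 alternatives, over which the median ran from -1.31 to -0.05 and the adjusted p from 0.0203 to 0.41. Of 7 lymphocyte genes 0 were called (median -0.58, adjusted p = 0.957). The lymphocyte median took both signs over 15 alternatives, from -1.13 to 0.50. Cd79b, a B cell receptor gene, stood at 13.4 ± 1.28 against 9.99 ± 1.47 CPM (adjusted p = 0.137). Over 17 alternatives the log2 fold change of Cd79b ran from -0.13 to 0.53, and 1 called it higher. Ptprc, which encodes the CD45 used to deplete leucocytes, stood at 1.38 ± 0.956 against 2.59 ± 2.17 CPM (adjusted p = 0.339). Counts adjusted over the list alone were the same for these 3 lists.

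Too few members passed the filter to test 6 lists. Krt15 stood for the 2 measured basal cell genes, at 0.375 ± 0.196 against 0.741 ± 0.241 CPM (adjusted p = 0.19). Syp, a synaptic vesicle gene among 3 neuroendocrine genes, was 3.32-fold lower at under 2 CPM and lies opposite another gene over 16.8% of its exon bases. G0s2 stood for 4 neutrophil genes (adjusted p = 0.725; lower in 1 of 17 alternatives). Of 4 sex-linked genes 0 were called, and Ddx3y stood at 90.7 ± 5.52 against 115 ± 20.8 CPM (adjusted p = 0.156). Its log2 fold change turned with the setting: without normal replicate 1 Ddx3y was lower (-0.48, adjusted p = 0.00193), and with the GC and length correction as well it was higher (0.22, adjusted p = 0.0364). No red cell gene passed the filter, and no mitochondrially encoded gene was in the table. Aldh1a7 lost its call in 7 of 17 alternatives, Syp in 5 of 16 and Dynlrb2 in 1 of 17 (adjusted p up to 0.149, 0.0915 and 0.0507).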

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

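Alternatives that corrected for GC content and length, or that used normal replicate 1 alone or left it out with that correction, were chosen after the data were seen; all others were planned. Of 63 named genes 25 kept their direction and their side of the threshold under every alternative and 23 lost their call under some. The fold changes of 8 took both signs over the alternatives, 0 of them called with all libraries: Cd79b, G0s2, Hnf1b, Id2, Ptprc, Sftpc, Mki67 and Ddx3y, of which the last 2 were called with the opposite sign. Of 31 gene lists 8 kept both under every alternative in which they were tested with the preset correlation. The medians of 10 lists took both signs, 0 of them called with all libraries, and 1 of the 10, mitosis, was called with the opposite sign. Of 47 called named genes 20 lost the call when 1 library was left out (adjusted p from 0.0502 to 0.158), and 0 were called in the opposite direction. Unless a cause is given, the cause was not tested.

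The count of genes higher was 512 with a minimum log2 change of 1, 2419 by DESeq2, 1531 with the GC and length correction and 4454 with normal replicate 1 left out and that correction, where 4 genes were called in the opposite direction. It ran from 189 to 4715 when 1 library was left out. The count of genes lower was 2832 by DESeq2 and 4010 with normal replicate 1 left out and the correction, and it ran from 471 to 4458 when 1 library was left out. Both extremes at the top came without normal replicate 1, and 820 of 820 higher and 1766 of 1768 lower genes were then called again. The correction called 721 of the 820 and 1520 of the 1768 again. With normal replicate 1 as the only normal library there were 691 higher and 1385 lower, of which 497 and 1045 were called with all libraries; the lone library is assumed there to vary as the mutant libraries do. The percent of called genes that were higher was 31.7, against 46.1 by DESeq2, 38.5 by limma-voom and 45.2 with the correction. Library size alone moved the median log2 fold change by 0.0826, and other scalings by less.

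Lists called higher and lower numbered 0 and 0 with an estimated correlation, and 7 and 6 by fry. Lists called lower numbered 8 with the GC and length correction and 10 with normal replicate 1 as the only normal library. When 1 library was left out, the transitional and type 2 lists kept their side of the threshold. The mitosis median was 1.65 with normal replicate 1 left out and the correction, from -0.83 to 1.54 when 1 library was left out (1.54 without normal replicate 1), and -1.56 with normal replicate 1 as the only normal library. DNA replication was at -0.97 in that last setting, and its median reached 0.62 over the alternatives. Mki67 was at 1.65 and Ddx3y at 0.22, both with normal replicate 1 left out and the correction.

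Kras passed by DESeq2 (-0.84, adjusted p = 0.0133), with no filter (-0.80, adjusted p = 0.0497) and with normal replicate 1 left out and the correction (-0.39, adjusted p = 0.00495). Its log2 fold change ran from -1.05 to -0.64 when 1 library was left out. The separation of the samples was 0.0667 with normal replicate 1 left out and the correction, and ran from -0.0222 to 0.0790 when 1 library was left out.

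The replicate number as a block gave 667 genes higher and 1223 lower, of which 545 and 1193 were called without it. With that block the interferon list lost its call (adjusted p = 0.103) and the inflammatory list gained one (adjusted p = 0.0229). With the block and the correction there were 1154 and 1459. Deviations from the group mean correlated at 0.122, 0.182 and 0.0741 between libraries of the same number, the highest value for each mutant library. Between libraries of different numbers they ran from -0.177 to 0.0761, the latter for normal replicate 3 with mutant replicate 2. These values lean toward a pairing by number without settling it, and the labels do not say what the numbers mark. The block was therefore kept as an alternative. In the simulation, with 3 libraries per group at this depth and spread, 2-fold changes were found in 10 of 50 genes and 4-fold changes in 43 of 50. Far fewer genes were changed there than were called here, so these shares need not hold for the real libraries.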

Other observations

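Tests chosen after their result was seen were those on endothelial and fibroblast RNA, on GC content and length, on the share of the main cell type, on a swap, on cycling leucocytes, on more stroma in normal replicates 2 and 3, and on the amino acid response. Only the tests on depth, imprinted genes and other splits of the libraries were written before their results.

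Genes of the amino acid response, which cells use when amino acids run short or proteins misfold, were in part higher in mutant cells. Asns, asparagine synthetase, had a log2 fold change of 2.60 ± 0.23 (SE, n = 3 per group), Mthfd2, a mitochondrial folate enzyme, 3.84 ± 0.39, and Chac1, a glutathione-degrading enzyme, 4.14 ± 0.22. Slc7a11, a cystine transporter, had 3.96, Trib3, a pseudokinase, 2.53 and Psat1, a serine synthesis enzyme, 1.85. These genes were named after their values were seen, and the 10 members noticed first had a median of 2.64. Of 30 other members, listed from textbook knowledge after the first 10 were noticed, 15 were higher and 0 lower, with a median of 0.71. Camera gave p = 1.02e-10 for these 30, unadjusted and 1 of 3 added lists tested, and p = 0.0313 with an estimated correlation. A candidate explanation is that the response as a whole was higher. Atf4, the response's main transcription factor, had 0.40 (adjusted p = 0.192) and Ddit3 0.24 (adjusted p = 0.389), so neither transcript was called.

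Dlk1, Rian and Meg3 lie in 1 imprinted locus and were all higher, with Meg3 at 263 ± 73.2 against 11.9 ± 8.05 CPM (log2 fold change 4.48). Meg3 was named after its values were seen. A general rise of imprinted genes might have produced this. For the libraries as a whole it was argued against: 21 measured imprinted genes outside the locus had a median log2 fold change of -0.54, with 1 called higher and 5 lower. Endothelial and fibroblast markers fell in the same libraries, with medians of -2.95 and -1.91. How much RNA of the 21 genes came from such cells was not measured, so a rise within epithelial cells alone stays open. Which allele of the locus was expressed was not analysed here.

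Endothelial and fibroblast markers were lower in the mutant libraries, 31 of 37 measured being called. A trend with GC content and length was argued against, since the endothelial median was -3.07 after correction. With all libraries the ciliated, club and macrophage medians lay at least 2.24 above the endothelial median, so these lists did not fall as far. The macrophage median moved with the setting, from -1.32 to 0.41 over 15 alternatives. The gap does not argue against a lower share of the main cell type in normal libraries. More endothelial and fibroblast RNA would itself lower that share. RNA from endothelial cells and fibroblasts, more of it in normal libraries, may account for the pattern. Within the mutant libraries 16 of 20 endothelial markers peaked in replicate 2. Random lists matched on mean expression had a median of 9 and a 95th percentile of 12. For fibroblast markers it was 11 of 17, against 8 and 10. Those lists were not matched on fold change. Mutant replicate 2 lay nearest the normal libraries on the first principal component (-58.2, against -72.1 and -64.2). Genes lower in mutant libraries could peak there whatever the cause, so the peaks cannot tell such RNA from lower expression within epithelial cells. The most abundant falling markers, Calcrl, Cdh5 and Bgn, stood at 718, 537 and 407 CPM in normal libraries, CD45 depletion would not remove such cells, and the marker of the sort is not named. Lower expression of these genes within mutant epithelial cells stays open and untested, as does the longer dissociation of lungs with neoplastic growth.

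Mitosis genes were highest in normal replicate 1, above normal replicates 2 and 3 by 2.98 on the log2 scale, and 29 of 30 members had their highest value of the 6 libraries there. A trend with GC content and length was argued against, since that difference was 3.02 after correction, and so was a swap with a mutant library, since on the endothelial list normal replicate 1 lay at 0.915 of the way from the mutant mean to normal replicates 2 and 3, with no mutant library above 0.117. Cycling leucocytes cannot be told apart from cycling cells of another kind: normal replicate 1 was highest on 2 of 3 leucocyte lists, by 0.09 for neutrophils and 0.44 for lymphocytes, and the lists are short, although leucocytes were depleted with CD45 beads and Ptprc, the gene for CD45, stood at 5.09 CPM there against 82.3 for Mki67. The labels give age and sex for no library. Ddx3y, a gene of the Y chromosome, stood at 86.1 to 130 CPM in all 6 libraries, and Xist did not pass the filter on low counts. These values argue against a difference in sex. Other biological explanations were not tested.

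Normal replicates 2 and 3 stood apart from normal replicate 1, and across genes their difference from it correlated with GC content at a Spearman rho of -0.450, against at most 0.113 in absolute size for other differences within a group. Lower depth was argued against, since thinning normal replicate 1 to the depth of normal replicate 2 left the correlation with GC content at -0.445. More endothelial cells and fibroblasts in normal replicates 2 and 3 were argued against as the whole cause, since 9.62% of the expressed genes exceeded the upper quartile of those markers, and Polr2a, a polymerase subunit gene, stood at 396, 3092 and 3159 CPM in normal replicates 1 to 3; that test replaced an earlier one, written beforehand, whose correlation of -0.449 among genes with small fold changes also counted against it, after its result was seen, because the earlier one left out called genes. A trend with GC content and length, of a kind that library preparation may give, was argued against as the whole cause, since removing it took that rho to -0.0156, yet normal replicate 1 still correlated with normal replicates 2 and 3 at 0.952 and 0.961, below the lowest other pair within a group (0.989, SD of those pairs 0.00267); it stays open as a part, and this test took the place of one on the rho alone after both results were seen. Apart from more endothelial cells and fibroblasts, and the sex-linked genes given above, no biological explanation was tested.

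The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 820 genes higher and 1768 lower, and as many came from 1 split, the real one, with the highest other at 0 in either direction. For gene lists the real split gave 6 higher and 5 lower, as many in 1 direction came from 9 of the 10 splits, and the highest other was 11. Camera with the preset correlation thus called lists under most splits. Every other split, however, put mutant and normal libraries on both sides. It kept part of the group difference between the sides and added the rest to the spread within them. Neither the gene counts nor the list counts of those splits therefore show how often calls arise without a group difference. By camera, which is not an exact test, of the 11 lists called in the real split only the endothelial list (p = 1.08e-29, against at lowest 2.69e-15 in another split) and NRF2 targets (p = 0.000251, against 0.000437) had their lowest p there.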
